A study of Mus musculus with 4 samples.

How the data were processed

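Single-nucleus RNA sequencing, which counts transcripts in isolated nuclei captured in droplets, was performed on non-tumor liver of male mice that had received diethylnitrosamine (DEN), a liver carcinogen, at 25 mg/kg at 14 days of age and were killed at 12 months. The 4 libraries fell into 2 groups by the genotype in the labels: 2 labelled Brca1-WT and 2 labelled Brca1-KO. The labels call them biological replicates and describe the mice no further, so p-values of single genes and shares measure the spread between these samples. The labels name a 10x Genomics 3′ v1 kit and give the molecule as genomic DNA, while the values are transcript counts. The deleted exons of Brca1 are not given in the sources used here.

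The deposited values were raw counts of unique molecular identifiers (UMIs) per gene and barcode, made with Cell Ranger 6.0.0 per the file headers and not normalized. Each deposited barcode held at least 500 UMIs. The submitters' processing notes name the genome build GRCh38, which is human, yet all 32285 gene identifiers in the deposited files are mouse identifiers. The mouse build is therefore not given in the sources used here, and no coordinates are printed. Gene order alone was taken from GENCODE vM21 (assembly GRCm38), where 32158 identifiers (99.6%) had a match. Whether intronic reads were counted, and whether counting used strand, is not given in the sources used here. Counts of near-identical paralogs (Cyp4a10, Cyp4a14 and Cyp4a31, the Acot genes, Cyp2b9 and Cyp2b13, Cyp2a4 and Cyp2a5, the Mup genes, Hspa1a and Hspa1b, Serpina1 genes) and of overlapping or antisense genes such as Brip1os and Ifngas1 are uncertain.

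All computed steps start from these counts. Nuclei with at least 500 detected genes and at most 5% mitochondrially encoded UMIs were kept. Doublets were called per library with Scrublet in scanpy 1.11.5 (expected rate 0.06, automatic thresholds of 0.136, 0.154, 0.196 and 0.245) and removed. The 4 libraries were clustered together without batch correction, using 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (python-igraph 0.11.9), which gave 23 clusters. A cluster was called "like" a cell class only from fixed markers: at least 3 markers detected in at least 10% of its nuclei, a score at least 1.5 times the next class, and no more markers of another class than of its own among its top 10 genes. The score rule was set after the data were seen. It left out 2 clusters with markers of 2 classes, holding 0.695% of the nuclei of the Brca1-WT libraries on average and 0.203% of those labelled Brca1-KO. No cluster was named cholangiocyte-like. Nuclei are not replicates, so UMIs were summed per library and class before testing, and a class was tested where each library held at least 30 nuclei.

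Sums were compared with edgeR 4.0.16 in R 4.3.3 (glmQLFit, robust, and glmQLFTest; TMM scaling; filterByExpr), as Brca1-KO minus Brca1-WT without a block. A gene passed at a Benjamini-Hochberg adjusted p below 0.05. Levels are TMM-normalised CPM, the counts scaled to a common library total. Single values per library were compared with a 2-sided exact permutation test, which cannot go below 0.33 with 2 libraries against 2. Shares carry exact Clopper-Pearson 95% intervals, and a count of 0 was read as allowing up to 3; both cover counting error only. For shares of nuclei with a Bhmt UMI, each nucleus was thinned to 1000 UMIs. Genes to be named were Brca1, Bhmt, up to 12 passing genes each way in hepatocyte-like nuclei and 5 each way in other sums, at an average log2 CPM of at least 3, with both libraries labelled Brca1-KO on the same side of both Brca1-WT libraries, leaving out mitochondrially encoded genes and unnamed models. Since none passed, the 5 each way with the smallest unadjusted p were taken, as the rule provides. In each gene list, up to 4 members of smallest unadjusted p were named. A few genes that these rules take are not reported here.

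Gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a family, and again with an estimated correlation and with fry. With the preset correlation, camera compares members with the other genes, so its p-values do not measure the spread between libraries. The 27 lists for hepatocyte-like nuclei were one-carbon and methionine cycle, homologous recombination and BRCA1 partners, p53 targets, proliferation, senescence, hepatocellular carcinoma and oncofetal markers, periportal and pericentral genes, xenobiotic metabolism, NRF2 response, lipogenesis, fatty acid oxidation and PPARA targets, cholesterol synthesis, bile acid synthesis and transport, gluconeogenesis and glycolysis, urea cycle and amino acid catabolism, male-biased and female-biased genes, acute phase, interferon response, inflammation, unfolded protein response, immediate early and heat shock genes, circadian clock, DNA methylation and histone modifiers, mitochondrially encoded genes and ribosomal proteins. Another 5 covered endothelial capillarization, scar macrophages, Kupffer cell identity, stellate cell activation, and T cell exhaustion and cytotoxicity. Of 931 list entries, 7 were not among the features. Groups, tests, lists, cell type markers, the rule for named genes and the alternatives were fixed before the data were examined; the alternative without the hepatocyte cluster of highest Gpc3 was added after.

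The fit was tested on simulated data drawn from the real means and library sizes and from dispersions of the fitted trend, with 200 genes changed. A gene's own dispersion, and a library that stands apart from the others, were not simulated. Recovery and false calls may therefore differ in the real libraries. For the comparison of hepatocyte-like nuclei (15089 genes), 5 of 97 genes changed by 2-fold and 63 of 97 changed by 4-fold were recovered, with 3 calls among 14860 unchanged genes. A planted list of 30 genes changed by 1.5-fold had an adjusted p of 2.5e-09, and 0 of 29 unchanged lists were called. These genes were drawn independently of each other and the lists at random. The estimated correlation was 0.88 for the real list of ribosomal proteins. The simulation therefore does not show how often correlated lists are falsely called. The alternatives were DESeq2 1.42.0, no filter on low counts, doublets kept, all deposited barcodes, Leiden resolution 0.5, nuclei thinned to 1000 UMIs (2000 and no thinning for Bhmt shares), a block on the replicate number, and each library left out in turn. Figures were drawn with matplotlib 3.10.9.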

Results

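Nuclei of non-tumor liver were profiled from male mice exposed to the carcinogen DEN, 2 libraries labelled Brca1-WT and 2 labelled Brca1-KO. The title of the series concerns an oncogenic role of hepatic Brca1, a DNA repair gene, acting through Bhmt, which encodes betaine-homocysteine methyltransferase, an enzyme that remethylates homocysteine to methionine. Pairs of values below are given for replicate 1 and then replicate 2. Where pairs are joined by "against", the libraries labelled Brca1-KO come first unless the groups are named. The deposited barcodes numbered 6841 and 7833 in the Brca1-WT libraries and 5209 and 6708 in the libraries labelled Brca1-KO, with 45638888, 40077856, 36662067 and 45076257 UMIs in the same order. After filters, 5802 and 6903 nuclei remained in the Brca1-WT libraries and 4781 and 6235 in those labelled Brca1-KO. Called doublets made up 11.9% and 8.22% of the nuclei that passed the other filters in the Brca1-WT libraries and 5.29% and 3.38% in those labelled Brca1-KO. Median UMIs per kept nucleus were 3522.5 and 3436 in the Brca1-WT libraries and 4319 and 4739 in those labelled Brca1-KO.

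Brca1 (ENSMUSG00000017146) was not lower in both libraries labelled Brca1-KO. In hepatocyte-like nuclei its level was 13.02 and 12.0 CPM in the Brca1-WT libraries, 18.5 CPM in the library labelled Brca1-KO replicate 1 and 6.13 CPM in the library labelled Brca1-KO replicate 2. The group means were 12.5 ± 0.750 and 12.3 ± 8.73 CPM (SD, n = 2 each; exact permutation p = 1.0). The log2 fold change was −0.02 with a standard error of 0.53 (edgeR adjusted p = 0.997). It was −1.04 without the library labelled Brca1-KO replicate 1 and 0.57 without the library labelled Brca1-KO replicate 2. In the sum of all nuclei the levels were 11.01 and 10.6 CPM in the Brca1-WT libraries and 17.1 and 6.12 CPM in those labelled Brca1-KO. In endothelial-like nuclei they were 2.39 and 4.68 CPM in the Brca1-WT libraries and 6.09 and 5.60 CPM in those labelled Brca1-KO. The assay counts tags near the 3′ end and the deleted exons are not given, so the gene's count may leave a deletion unseen. Every direction below rests on the labels as given.

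Bhmt (ENSMUSG00000074768) was lower in both libraries labelled Brca1-KO in hepatocyte-like nuclei, at 717 and 288 CPM against 1877 and 1190 CPM in the Brca1-WT libraries. The means were 503 ± 303 and 1534 ± 486 CPM (SD, n = 2 each), a ratio of 0.328, and the exact permutation p was 0.33, the smallest that 2 against 2 libraries can give. The log2 fold change was −1.61 with a standard error of 0.53 and did not pass (edgeR unadjusted p = 0.028, adjusted p = 0.99). Without the library labelled Brca1-KO replicate 1, the log2 fold change was −2.42 with an adjusted p of 0.030. It was −1.90 without Brca1-WT replicate 2, −1.25 without Brca1-WT replicate 1 (unadjusted p = 0.127) and −1.09 without the library labelled Brca1-KO replicate 2, and none of these passed. With each nucleus thinned to 1000 UMIs, 72.3% (95% interval 70.5 to 73.9%) and 61.6% (60.0 to 63.1%) of hepatocyte-like nuclei in the Brca1-WT libraries held a Bhmt UMI. The shares were 46.0% (44.1 to 48.0%) and 20.8% (19.5 to 22.1%) in the libraries labelled Brca1-KO. The mean difference was −33.5 percentage points (exact permutation p = 0.33). Thinning left out 33 and 12 shallower hepatocyte-like nuclei of the Brca1-WT libraries and 7 and 21 of those labelled Brca1-KO. Unthinned, the mean shares were 94.0% in the Brca1-WT libraries and 78.3% in those labelled Brca1-KO. The median depths were 8783 and 5924 UMIs, and 9507 and 7354 UMIs, in the same order of groups. Endothelial-like nuclei, which should lack Bhmt, gave a background after the same thinning. It was 24.7% and 21.7% in the Brca1-WT libraries and 12.9% and 10.7% in those labelled Brca1-KO. This thinning left out 88 and 374 endothelial-like nuclei of the Brca1-WT libraries and 198 and 162 of those labelled Brca1-KO. Their median depths before any thinning were 1849 and 1400 UMIs, and 1511.5 and 1253 UMIs, in the same order of groups. The hepatocyte-like nuclei of the library labelled Brca1-KO replicate 2 lay mostly in clusters 4, 6 and 13, which held 3525 of its 4079 nuclei (86.4%), against 4.06% and 1.77% of those in the Brca1-WT libraries and 0.351% in the library labelled Brca1-KO replicate 1. This holds for every hepatocyte value given here.

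**Figure D1:**
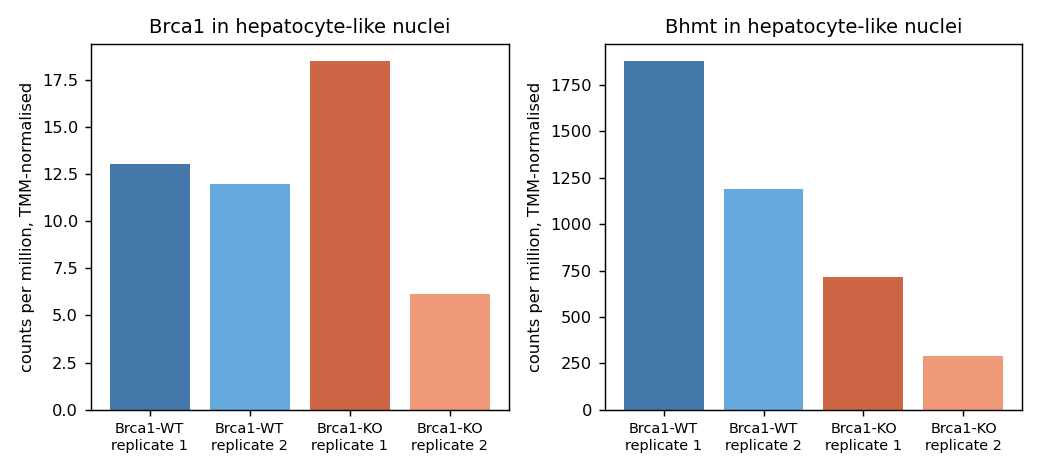
Levels of Brca1 (left) and Bhmt (right) in the summed hepatocyte-like nuclei of each library, in TMM-normalised CPM, each bar 1 library. Brca1 ranged from 6.13 to 18.5 CPM with both extremes in libraries labelled Brca1-KO, while Bhmt was 717 and 288 CPM in those libraries against 1877 and 1190 CPM.

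Other genes of the methionine cycle were not called as a list. Of 29 measured one-carbon genes, 18 were lower and 11 higher in the libraries labelled Brca1-KO, with a median log2 fold change of −0.09 (camera adjusted p = 0.21). The neighbouring family member Bhmt2 had 187 and 170 CPM against 298 and 250 CPM, and Dmgdh, which oxidises the dimethylglycine that Bhmt releases, 307 and 328 against 506 and 407 CPM. Mat2a, an S-adenosylmethionine synthetase, had 81.1 and 94.5 against 64.5 and 70.9 CPM. None of the 29 passed adjusted over the list alone. The list was called lower without the library labelled Brca1-KO replicate 1 (adjusted p = 0.0014).

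Among genes that the naming rule admits, the 5 higher ones of smallest unadjusted p in hepatocyte-like nuclei did not pass. Nebl, encoding the actin-binding protein nebulette, had 13.8 and 16.3 CPM against 4.71 and 4.2 CPM (log2 fold change 1.75, standard error 0.23). Slc15a2, a peptide transporter, had 18.1 and 26.8 against 8.75 and 5.69 CPM (1.64, standard error 0.33). Syvn1, an E3 ubiquitin ligase of the endoplasmic reticulum, had 71.2 and 69.7 against 36.7 and 27.1 CPM. Banp had 203 and 229 against 107 and 107 CPM, and Lnx1, a ubiquitin ligase, 107 and 119 against 54.5 and 61.1 CPM. Of the 5 lower genes, Thsd4 had 0.75 and 0.547 CPM against 66.7 and 19.7 CPM, and Cyp2b9, a cytochrome P450 of female-biased expression, 8.42 and 11.6 against 98.3 and 51.2 CPM. Sntg2, a syntrophin, had 66.6 and 93.6 against 445 and 252 CPM. The acyl-CoA thioesterase Acot1 had 7.81 and 8.45 against 24.0 and 21.9 CPM, and Acsl5, a long-chain acyl-CoA synthetase, 51.2 and 56.0 against 102 and 102 CPM.

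Of 15089 genes tested in hepatocyte-like nuclei, 0 passed edgeR's test (smallest adjusted p = 0.23), while 495 had an unadjusted p below 0.05, where chance gives 754, 152 of them higher and 343 lower. DESeq2 called 23, of which 9 were higher and 14 lower; they included Nebl, Slc15a2, Thsd4, Cyp2b9, Sntg2 and Acot1. The groups did not overlap for 4850 genes (32.1%), where chance gives 33.3%. Without the library labelled Brca1-KO replicate 1, edgeR called 198 genes, on the assumption that the lone remaining library of that label varies as the other group does. A cluster of 173 nuclei, cluster 15, was led by Cyp2b9, Cacna1b, Cdh1, Gpc3, Thsd4 and Cyp2a4 and drew 150 and 22 nuclei from the Brca1-WT libraries. It held 0 of 2563 hepatocyte-like nuclei of the library labelled Brca1-KO replicate 1, which allows a share of up to 0.117%, and 1 nucleus of replicate 2. Without it, the log2 fold change went from −6.06 to −0.99 for Thsd4 and from −2.90 to −1.3 for Cyp2b9, and it was −1.55 for Acot1, −2.18 for Sntg2 and −1.67 for Bhmt.

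**Figure D2:**
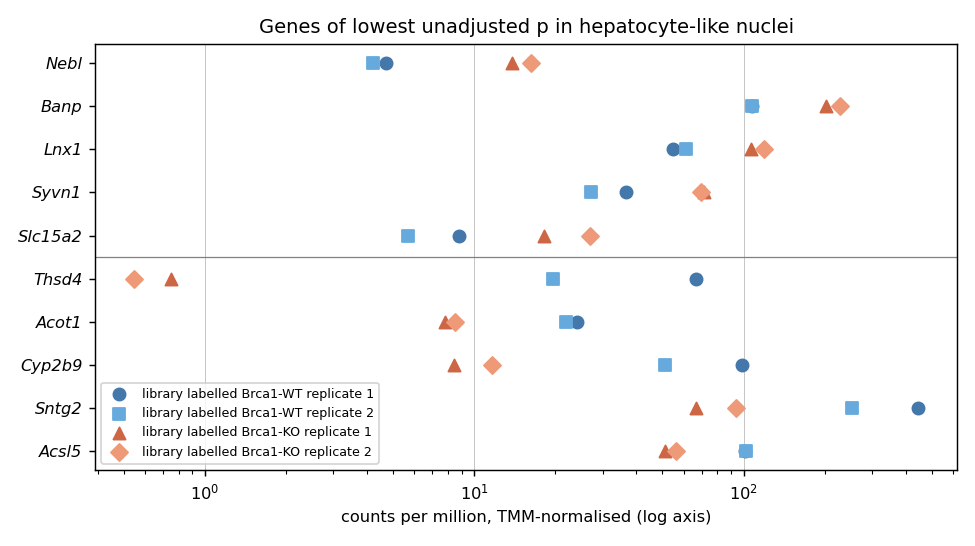
Level in each library of 10 genes in hepatocyte-like nuclei, in TMM-normalised CPM on a log axis. They are the 5 each way of smallest unadjusted p among genes that the naming rule admits. Each point is 1 library and none of the genes passed. For Nebl the libraries labelled Brca1-KO had 13.8 and 16.3 CPM against 4.71 and 4.2 CPM, and for Acot1 7.81 and 8.45 against 24.0 and 21.9 CPM.

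By camera with the preset correlation, 6 of the 27 lists were called in hepatocyte-like nuclei, 1 higher and 5 lower, and 0 with an estimated correlation (smallest adjusted p = 0.51) or with fry. The count of lists was 11 without Brca1-WT replicate 2, 11 without the library labelled Brca1-KO replicate 1 and 16 without the library labelled Brca1-KO replicate 2. Genes of fatty acid oxidation and PPARA targets fell as a list (adjusted p = 9.4e-10; adjusted p = 0.51 with an estimated correlation). Of 32 members, 26 were lower with a median log2 fold change of −0.38, and in 16 both libraries labelled Brca1-KO were below both Brca1-WT libraries. The fatty acid omega-hydroxylases Cyp4a14 and Cyp4a10 had 651 and 242 against 1152 and 1838 CPM, and 251 and 72.6 against 498 and 760 CPM, and Cyp4a31 had 4.74 and 2.76 against 8.95 and 8.23 CPM. Of these members 0 passed over all genes by edgeR, 8 had an unadjusted p below 0.05, and 1, Acot1, passed adjusted over the list alone. A list of 13 genes raised by fasting, written after the data were seen and sharing Cyp4a10 and Cyp4a14 among others with this one, was not tested between the groups. Its median log2 ratio to the other 3 libraries was 0.62 and 0.37 in the Brca1-WT libraries and −0.08 and −1.17 in those labelled Brca1-KO.

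Genes of the unfolded protein response, which acts on misfolded protein in the endoplasmic reticulum, rose as a list (adjusted p = 8.6e-10; adjusted p = 0.61 with an estimated correlation). Of 27 members, 21 were higher, with a median log2 fold change of 0.45, and 13 were above both Brca1-WT libraries in both libraries labelled Brca1-KO. Beside Syvn1, the chaperone cofactor Sdf2l1 had 1.02 and 2.52 against 0.572 and 0.271 CPM. Creld2 had 12.5 and 24.5 against 9.96 and 4.2 CPM, and the disulfide isomerase Pdia6 36.5 and 99.96 against 31.1 and 13.2 CPM. None passed adjusted over the list alone.

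Transcripts of the mitochondrial genome fell as a list (adjusted p = 1.2e-09; adjusted p = 0.61 with an estimated correlation). All 13 were lower, 12 of them in both libraries labelled Brca1-KO below both Brca1-WT libraries, with a median log2 fold change of −0.59. The complex I subunits mt-Nd4 and mt-Nd1 had 55.1 and 52.9 against 87.2 and 88.8 CPM, and 39.2 and 44.5 against 71.4 and 64.5 CPM. The cytochrome oxidase subunits mt-Co2 and mt-Co1 had 91.9 and 99.9 against 134 and 155 CPM, and 225 and 251 against 347 and 382 CPM. Their median share of UMIs over all kept nuclei was 0.110% and 0.102% in the libraries labelled Brca1-KO against 0.195% and 0.148% in the Brca1-WT libraries. These transcripts are made outside the nucleus, and their share served as a filter on nuclei. A difference in preparation between libraries was not told apart from a change of expression in hepatocytes. Ribosomal protein transcripts also fell as a list, with 36 of 37 lower and a median of −0.28 (adjusted p = 0.00018; adjusted p = 0.69 with an estimated correlation). This call was lost without Brca1-WT replicate 2 (adjusted p = 0.765, with the opposite direction) and without the library labelled Brca1-KO replicate 2 (0.269). Both libraries labelled Brca1-KO lay below both Brca1-WT libraries in only 6 of the 37. The median log2 ratio to the Brca1-WT mean was −0.28 in Brca1-WT replicate 1 itself. It was −0.16 and −0.40 in the libraries labelled Brca1-KO. Among the 6, Rpl4 had 14.3 and 11.8 against 16.1 and 19.1 CPM, Rps6 18.9 and 17.4 against 20.5 and 27.5 CPM and Rps29 16.2 and 14.9 against 16.7 and 25.0 CPM. None of either list passed adjusted over the list alone.

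Female-biased liver genes fell as a list (adjusted p = 0.00018; adjusted p = 0.61 with an estimated correlation), with 13 of 19 lower and a median of −0.31. Cyp2b9 passed adjusted over the list alone. Cyp2a4 had 0.102 and 0.192 against 11.4 and 0.441 CPM, the thioesterase Acot3 4.33 and 13 against 29.0 and 24.5 CPM, and the fatty acid transporter Cd36 9.0 and 31.1 against 6.83 and 8.20 CPM. Markers of hepatocellular carcinoma and oncofetal genes fell as a list too (adjusted p = 0.034; adjusted p = 0.61 with an estimated correlation). Of its 16 members 9 were lower, with a median of −0.21 and a mean of −1.07. Gpc3, an oncofetal proteoglycan, had 0.239 and 0.301 against 19.01 and 1.66 CPM, Tspan8 0 and 0.0547 against 3.47 and 0.441 CPM, and Akr1c18 0.170 and 0.465 against 3.06 and 0.983 CPM. Sox9, a progenitor and duct marker, had 5.11 and 4.92 against 3.10 and 3.35 CPM. None passed adjusted over the list alone. Without cluster 15 the log2 fold change went from −5.23 to −0.90 for Gpc3 and from −2.63 to −0.31 for Akr1c18, and the adjusted p was 0.134 for the female-biased and 0.936 for the carcinoma list. The lists called then still numbered 6, with pericentral genes (0.045, lower) and immediate early and heat shock genes (0.032, higher) in addition. The carcinoma list was also lost without Brca1-WT replicate 1 (0.066) and, with the opposite direction, in thinned nuclei (0.635).

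**Figure D3:**
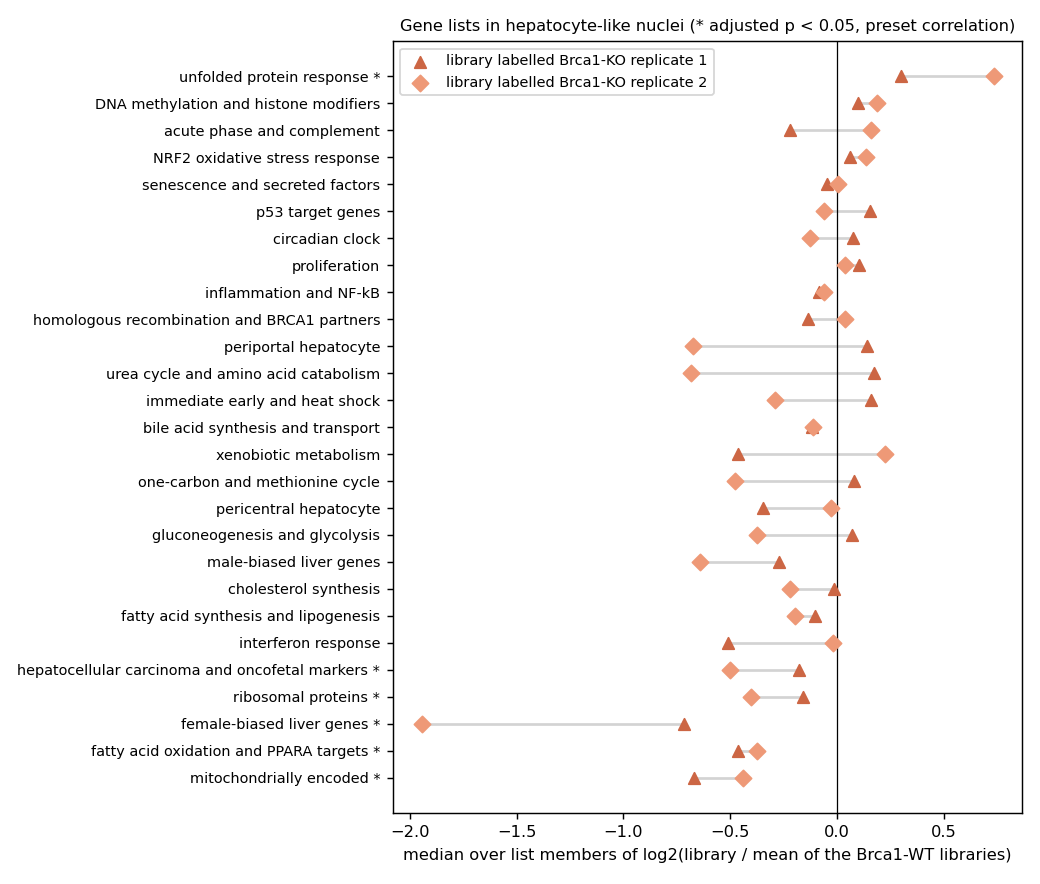
Median over the measured members of each of the 27 lists of the log2 ratio of a library labelled Brca1-KO to the mean of the Brca1-WT libraries in hepatocyte-like nuclei (horizontal axis), each mark 1 library; an asterisk marks an adjusted p below 0.05 by camera with the preset correlation. The unfolded protein response stood at 0.30 and 0.73, fatty acid oxidation at −0.46 and −0.38, and the urea cycle list at 0.17 and −0.69.

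The other lists of liver zonation and metabolism were not called in the main test, and several differed between the libraries labelled Brca1-KO. The median log2 ratio to the Brca1-WT mean was 0.17 and −0.69 for urea cycle and amino acid catabolism (adjusted p = 0.222), 0.14 and −0.68 for periportal genes (0.987) and −0.35 and −0.03 for pericentral genes (0.092). For the alternatives that changed the nuclei or libraries used, list results here and elsewhere are given at the preset correlation. Those calls do not measure the spread between libraries. The correlation estimated in the main test was 0.45 for the urea cycle list, 0.16 for periportal and 0.25 for pericentral genes. Without the library labelled Brca1-KO replicate 1 the urea cycle and periportal lists were called lower. Without the library labelled Brca1-KO replicate 2 the urea cycle and periportal lists were called higher and the pericentral list lower. The pericentral list was also called lower without Brca1-WT replicate 2, in thinned nuclei (camera adjusted p = 0.0040) and without cluster 15 (0.045). In the main test the periportal list pointed up, with a median of −0.05 and a mean of 0.07. Tat, a tyrosine aminotransferase, had 2124 and 807 against 2331 and 2051 CPM, Oat 57.4 and 17.8 against 55.2 and 60.5 CPM, Haao 219 and 177 against 206 and 277 CPM and Otc 239 and 332 against 204 and 236 CPM. Of periportal genes, Pck1 had 2210 and 1719 against 2527 and 2996 CPM, Ctsc 27.8 and 50.1 against 29.4 and 24.0 CPM, Mup20 112 and 151 against 95.5 and 109 CPM and Serpina12 0.409 and 1.29 against 0.135 and 0.0339 CPM. Of pericentral genes, Gulo had 56.6 and 43.9 against 95.9 and 86.1 CPM, Cyp2c37 158 and 92.6 against 256 and 246 CPM, Glul, glutamine synthetase, 84.0 and 124 against 191 and 131 CPM and Cyp2c50 36.6 and 84.5 against 121 and 89.6 CPM.

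Gluconeogenesis and glycolysis genes were not called (adjusted p = 0.092; 0.0075 without the library labelled Brca1-KO replicate 1, 0.0496 with doublets kept and 0.047 with all barcodes). G6pc, the last enzyme of glucose release, had 404 and 122 against 1070.4 and 417 CPM and Pdk4 4.09 and 2.05 against 7.94 and 4.78 CPM. Lipogenesis had an adjusted p of 0.194, with 0.015 without Brca1-WT replicate 2 and 0.0017 without the library labelled Brca1-KO replicate 2. Elovl5 had 70.5 and 53.9 against 116 and 133 CPM, Thrsp 2.32 and 2.65 against 9.89 and 3.96 CPM and Me1 171 and 241 against 115 and 152 CPM. Cholesterol synthesis had an adjusted p of 0.210, with 0.016 in thinned nuclei, and Insig2 had 209 and 136 against 477 and 257 CPM. Bile acid synthesis and transport had 0.092, with 0.026 without the library labelled Brca1-KO replicate 2 and 0.0058 in thinned nuclei. Its transporters Slco1a1 and Slco1a4 had 307 and 135 against 673 and 467 CPM, and 509 and 485 against 1118 and 757 CPM, and Cyp8b1, the sterol 12-alpha-hydroxylase, 33.0 and 35.8 against 48.6 and 53.9 CPM. Xenobiotic metabolism had 0.117, with 0.014 without Brca1-WT replicate 1 and 4.4e-08 without the library labelled Brca1-KO replicate 2, and 1 member, Cyp2b9, passed adjusted over the list alone. Male-biased genes had 0.222, and 0.0049 without Brca1-WT replicate 2; Cyp2d9 had 191 and 157 against 258 and 262 CPM and Serpina1e 6.14 and 44.7 against 5.28 and 4.17 CPM. Apart from Cyp2b9, none of these passed adjusted over the list alone.

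Lists of DNA repair and growth showed no call in the main test. Homologous recombination genes and BRCA1 partners had 17 of 29 lower (adjusted p = 0.518), with Brca2 at 13.4 and 14.1 against 20.4 and 23.8 CPM. The p53 targets had an adjusted p of 0.553, and 0.0026 without the library labelled Brca1-KO replicate 2. Proliferation genes also had 0.553, with 11 of 20 higher. Anln had 0.682 and 0.465 against 4.27 and 0.847 CPM, whereas E2f1 had 1.26 and 2.33 against 0.841 and 1.25 CPM and Aspm 0.716 and 1.40 against 0.538 and 0.678 CPM. Senescence genes had 0.987, with the lysosomal galactosidase Glb1 at 15.4 and 16.0 against 25.7 and 24.0 CPM. DNA methylation and histone modifiers had 0.072, and 0.014 without the filter on low counts, with 23 of 30 higher and Kmt2a at 204 and 224 against 152 and 175 CPM. None of these members passed adjusted over the list alone.

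The remaining stress, immune and clock lists were not called in the main test either. Immediate early and heat shock genes had an adjusted p of 0.299, and 0.032 (higher) without cluster 15, with a test pointing up, a median of −0.05 and a mean of 0.06. Of them the heat shock genes Hsp90aa1 and Hsph1 had 62.9 and 100.1 against 33.7 and 38.7 CPM, and 75.9 and 171 against 22.5 and 45.1 CPM, and Nr4a1, an immediate early gene, 0.818 and 0.492 against 1.68 and 2.20 CPM. The interferon response had 0.210, with Rsad2 at 2.90 and 3.01 against 0.774 and 0.474 CPM and H2-K1 at 115 and 115 against 168 and 155 CPM. The NRF2 response had 0.157, with Osgin1 at 52.6 and 152 against 37.2 and 46.4 CPM, and the circadian clock 0.157, with Nr1d1 at 24.3 and 44.5 against 19.01 and 14.1 CPM. Acute phase genes had 0.987 (test up, median 0.09, mean −0.06), with Itih4 at 98.7 and 233 against 89.7 and 80.6 CPM, and inflammation 0.992 (test down, median −0.01, mean 0.03), with Cxcl1 at 3.21 and 19.7 against 4.68 and 3.83 CPM. None passed adjusted over the list alone. The interferon list was lower with doublets kept (0.020), with all barcodes (0.021) and in thinned nuclei (0.045). Without Brca1-WT replicate 2 the interferon list was called lower and the NRF2 and clock lists higher. Without the library labelled Brca1-KO replicate 2 the interferon and acute phase lists were called lower and the clock and immediate early lists higher. The acute phase list was called higher without the library labelled Brca1-KO replicate 1. These calls used the preset correlation and do not measure the spread between libraries. The correlation estimated in the main test was 0.38 for the interferon list.

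In none of the 6 classes tested for gene expression did the shares of nuclei separate the groups. Hepatocyte-like nuclei made up 52.5 ± 6.89% of the Brca1-WT libraries and 59.5 ± 8.35% of those labelled Brca1-KO (SD, n = 2 each; exact permutation p = 0.67). Endothelial-like nuclei made up 24.8 ± 3.03% and 17.8 ± 10.1% (exact permutation p = 0.67), with 24.9% in the library labelled Brca1-KO replicate 1 and 10.7% in replicate 2. Of the 666 endothelial-like nuclei of the latter, 451 lay in the shallow cluster 10. Macrophage-like nuclei made up 6.27 ± 0.278% and 7.61 ± 1.62%, with 6.4633% in Brca1-WT replicate 1 and 6.4631% in the library labelled Brca1-KO replicate 1. Stellate- or fibroblast-like nuclei made up 8.31 ± 0.507% and 8.31 ± 0.362%, T- or NK-like nuclei 3.6 ± 0.908% and 3.05 ± 0.749% and B-like nuclei 2.23 ± 0.896% and 1.93 ± 0.513%, with an exact permutation p of at least 0.67 for each of these classes. At Leiden resolution 0.5, with doublets kept and with all barcodes, both libraries labelled Brca1-KO lay above both Brca1-WT libraries in the macrophage-like share (exact permutation p = 0.33). The remaining named classes were under 2% in each library. Among them both libraries labelled Brca1-KO lay above both Brca1-WT libraries for plasmacytoid dendritic cell-like nuclei (10 and 12 against 8 and 3 nuclei) and plasma cell-like nuclei (10 and 15 against 11 and 11 nuclei). Their mean shares were 0.201% against 0.0907% and 0.225% against 0.175%, each with an exact permutation p of 0.33, the smallest possible here. The libraries differed in doublet calls and depth, which can set such shares.

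**Figure D4:**
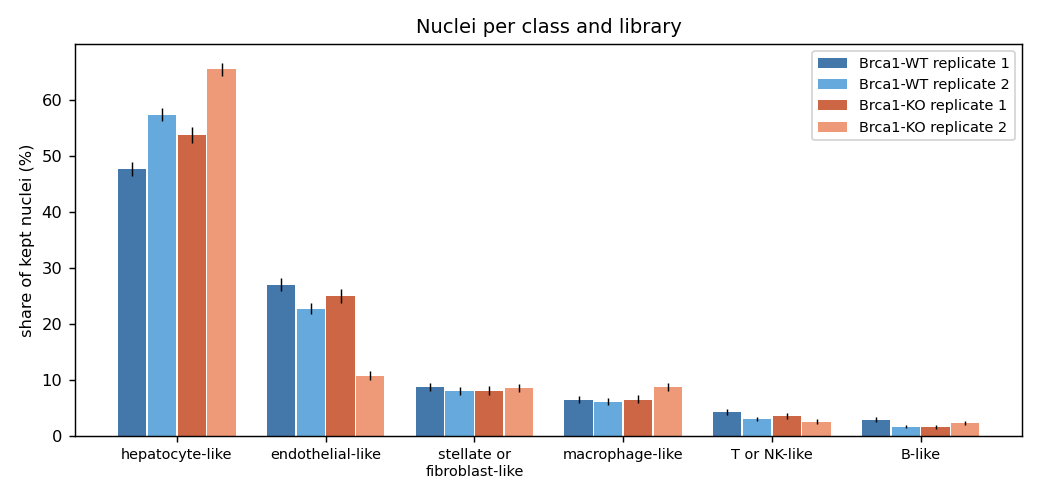
Share of kept nuclei in 6 classes (vertical axis, percent), each bar 1 library with its exact 95% binomial interval, which covers counting error only. The hepatocyte-like share was highest (65.4%) and the endothelial-like share lowest (10.7%) in the library labelled Brca1-KO replicate 2.

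In endothelial-like nuclei, genes of capillarization and activation fell as a list (adjusted p = 0.013; adjusted p = 0.31 with an estimated correlation), with 17 of 26 lower. The shallow cluster 10, with a median of 933 UMIs, held 451 of 666 endothelial-like nuclei of the library labelled Brca1-KO replicate 2, against 98 of 1564 and 279 of 1565 in the Brca1-WT libraries and 146 of 1192 in the library labelled Brca1-KO replicate 1. Wnt2, a ligand of central vein endothelium, had 90.4 and 73.9 against 157 and 105 CPM, the receptor Kit 139 and 137 against 224 and 161 CPM, the transcription factor Maf 1486 and 1041 against 2279 and 1587 CPM and Thbd, thrombomodulin, 8.63 and 4.48 against 16.1 and 9.75 CPM. Wnt2, Kit, Maf and Thbd are known in sinusoidal or vascular endothelium at rest as well as after activation. The list also holds markers that served to name the class, such as Stab2 and Clec4g. A fall of the list therefore does not tell less capillarization from more. No member passed adjusted over the list alone, and the call was lost without Brca1-WT replicate 2 (0.320) and without the library labelled Brca1-KO replicate 2 (0.549). Of single genes, Stac2 had 25.9 and 22.4 against 4.78 and 9.75 CPM, Lnx1 14.2 and 31.3 against 4.48 and 5.85 CPM, Cotl1 72.6 and 95.1 against 43.9 and 41.7 CPM, Tmem25 18.8 and 32.5 against 7.77 and 10.1 CPM and Kynu 361 and 513 against 255 and 211 CPM. Lower were Gbp8 with 15.7 and 13.4 against 44.8 and 29.2 CPM, Atpif1 with 9.14 and 12.3 against 24.5 and 24.9 CPM and Brip1os with 43.7 and 35.8 against 87.5 and 70.9 CPM, beside the hepatocyte genes Cyp4a10, Slco1a1 and Bhmt, the last with 151 and 143 against 294 and 265 CPM. By edgeR 0 of 11127 genes passed, 275 had an unadjusted p below 0.05, where chance gives 556, and DESeq2 called 0. EdgeR called 587 without the library labelled Brca1-KO replicate 1 and 3 without replicate 2.

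In macrophage-like nuclei, genes of resident Kupffer cell identity fell as a list (adjusted p = 0.0066; adjusted p = 0.24 with an estimated correlation), with 14 of 19 lower. The list also holds markers that served to name the class, such as Cd5l and Timd4, so its fall alone does not show a loss of identity. Cd5l had 985 and 1209 against 1923 and 1685 CPM, the transcription factor Spic 79.3 and 55.5 against 91.2 and 150.5 CPM, C6, a complement component, 1185 and 770.3 against 1428 and 1722 CPM and the phosphatidylserine receptor Timd4 386 and 533 against 553 and 779 CPM. None passed adjusted over the list alone. The direction turned when doublets were kept (0.918) or all barcodes used (0.971), and the call was lost without Brca1-WT replicate 2 (0.320) and without the library labelled Brca1-KO replicate 2 (0.057). Scar macrophage genes were not called (0.682), with Mmp12 at 172 and 26.5 against 23.5 and 5.68 CPM, Mmp14 at 7.38 and 12.1 against 20.7 and 72.4 CPM and none passing adjusted over the list alone. Alcam, an adhesion molecule, had 196 and 300.2 against 78.7 and 85.2 CPM, Plxdc1 90.4 and 157 against 11.1 and 38.3 CPM and Arhgap10 332 and 323 against 195 and 182 CPM. Naa16 and Ptpn3 were also higher. Dpp6 had 16.6 and 14.5 against 67.7 and 75.2 CPM and Ly6m 3.69 and 4.82 against 23.5 and 29.8 CPM, with AU019990 and the hepatocyte genes Cyp4a10 and Cyp4a14 also lower. The lower Ly6m values rest on a few UMIs, as the sums of the libraries labelled Brca1-KO held 560936 and 896674 UMIs. By edgeR 0 of 8295 passed, 361 had an unadjusted p below 0.05, where chance gives 415, and DESeq2 called 0. The count was 530 without the library labelled Brca1-KO replicate 1, without replicate 2 it was 57 and without Brca1-WT replicate 1 it was 18.

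In stellate- or fibroblast-like nuclei, genes of stellate activation and matrix rose as a list (adjusted p = 0.032; adjusted p = 0.24 with an estimated correlation), with 17 of 24 higher. The list also holds markers that served to name the class, such as Lrat and Reln, so its rise alone does not show activation. The collagens Col4a1 and Col6a3 had 175 and 205 against 152 and 118 CPM, and 194 and 183 against 155 and 139 CPM. Col3a1 had 133 and 358 against 168 and 112 CPM and Ccn2, a matricellular factor, 149 and 46.8 against 46.6 and 59.7 CPM. No member passed adjusted over the list alone, and the call was lost without Brca1-WT replicate 2 (0.320), without the library labelled Brca1-KO replicate 1 (0.072), without replicate 2 of that label (0.076) and in thinned nuclei (0.510). Fbxl13 had 33.2 and 17.2 against 2.33 and 3.06 CPM, Slc15a2 63.2 and 50.0 against 14.8 and 21.4 CPM and the co-chaperone Stip1 36.4 and 59.3 against 16.3 and 19.9 CPM, with Gfod1 and Unc13b also higher. The Fbxl13 values of the Brca1-WT libraries rest on a few UMIs, from sums of 1270248 and 1328270 UMIs. Colec11, a collectin of stellate cells, had 250 and 255 against 549 and 487 CPM and Adgrl3, an adhesion receptor, 46.1 and 34.3 against 116 and 97.2 CPM, with Csmd1, Mfsd2a and the hepatocyte gene Cyp2c37 also lower. By edgeR 0 of 9715 passed, 391 had an unadjusted p below 0.05, where chance gives 486, and DESeq2 called 0. The count was 406 without the library labelled Brca1-KO replicate 1 and 51 without replicate 2.

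In T- or NK-like nuclei, genes of T cell exhaustion and cytotoxicity rose as a list (adjusted p = 0.032; adjusted p = 0.24 with an estimated correlation), with 11 of 12 higher. The list also holds Ccl5, a marker that served to name the class. Cd244a had 161 and 135 against 75.8 and 79.4 CPM and Ccl5 236 and 184 against 114 and 169 CPM, while Tox, an exhaustion regulator, had 1234 and 1015 against 1499 and 2208 CPM. None passed adjusted over the list alone. The call was lost without each library in turn: 0.252 and 0.754 without Brca1-WT replicates 1 and 2, 0.840 with the opposite direction without the library labelled Brca1-KO replicate 1, and 0.544 without replicate 2 of that label. It was also lost without the filter on low counts (0.398), in thinned nuclei (0.444) and at Leiden resolution 0.5 (0.091). That resolution moved 1 nucleus of Brca1-WT replicate 1 to the hepatocyte-like class, which took the class in that library from 246 to 245 nuclei and from 396198 to 371802 UMIs. Slc15a2 had 82.5 and 85.4 against 8.12 and 23.2 CPM, with Ifngas1, Gpc4, Chsy3 and Pdia3 also higher. The 8.12 CPM of Brca1-WT replicate 1 rests on a few UMIs, as its sum held 396198 UMIs. Il23r, the interleukin 23 receptor, had 11.2 and 17.97 against 138 and 72.8 CPM. Trps1 and the hepatocyte genes Slco1a1, Cyp2c37 and Cyp4a10 were also lower. By edgeR 0 of 5952 passed, 161 had an unadjusted p below 0.05, where chance gives 298, and DESeq2 called 0; without the library labelled Brca1-KO replicate 1 the count was 88 and without replicate 2 it was 6.

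In B-like nuclei, Ppp1r9a had 151 and 170 CPM against 26.7 and 36.4 CPM and Gcnt2, a glycosyltransferase, 254 and 229 against 57.8 and 87.5 CPM. Atp8b1 was also higher, as were Slc1a2 and Sardh, which are on hepatocyte lists. Agbl1 had 7.93 and 29.4 against 475 and 168 CPM and Dstyk 23.8 and 23.5 against 93.3 and 124 CPM. The B-like sums held 143752 and 211444 UMIs in the libraries labelled Brca1-KO and 260149 and 158314 in the Brca1-WT libraries. The lowest values of Agbl1 and Dstyk therefore rest on a few UMIs. Tnfaip8 and the hepatocyte genes G6pc and Cyp4a14 were also lower. By edgeR 0 of 4199 genes passed, 399 had an unadjusted p below 0.05, where chance gives 210, and DESeq2 called 0. The groups did not overlap for 40.7% of genes, where chance gives 33.3%. The count was 133 without the library labelled Brca1-KO replicate 1, 2 without Brca1-WT replicate 1 and 35 without Brca1-WT replicate 2. In the sum of all nuclei, 0 of 17127 genes passed by edgeR, 807 had an unadjusted p below 0.05, where chance gives 856, DESeq2 called 21 and edgeR called 182 without the library labelled Brca1-KO replicate 1. In that sum the groups did not overlap for 6756 genes (39.4%), where chance gives 33.3%. The named genes there were Slc15a2 (31.9 and 30.8 against 10.1 and 10.4 CPM), Nebl, Syvn1, Lnx1 and Banp on the higher side and Cyp2b9, Acot1, Colec11, Thsd4 and Sntg2 on the lower, each with an edgeR adjusted p of 0.80.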

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

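All of the following results were picked because both libraries labelled Brca1-KO lay above both Brca1-WT libraries in 1 class and below them in another. The differences between classes were not tested, and some picks rest on near ties or low levels. In endothelial-like nuclei, Acsl5 had 39.09 CPM in the library labelled Brca1-KO replicate 1 against 38.84 CPM in Brca1-WT replicate 1. For Cotl1 in stellate- or fibroblast-like nuclei, the same libraries had 8.572 against 8.542 CPM. In macrophage-like nuclei, Igfbp7 had 1.845 CPM in the library labelled Brca1-KO replicate 1. Over all genes measured in a pair of classes, 2.3 to 4.94% lay on opposite sides and 6.81 to 10.0% on the same side. Chance gives 5.56% for each if the classes are independent. They come from the same libraries, so a difference from that value does not show an effect of the group.

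Between hepatocyte-like and other nuclei, the log2 fold change was −0.41 against 0.32 in B-like nuclei for Abcb4, −0.52 against 0.22 in B-like nuclei for Dmgdh and −0.49 against 0.20 in B-like nuclei for Pck1. For Acsl5 it was −0.93 against 0.32 in endothelial-like and 0.36 in stellate- or fibroblast-like nuclei. For Orm1 it was −0.58 in hepatocyte-like, 1.07 in macrophage-like and −1.10 in T- or NK-like nuclei, and both pairs with macrophage-like nuclei were picked. For Rpl4 it was −0.43 in hepatocyte-like and 1.06 in T- or NK-like nuclei. For Rps6 it was −0.40 in hepatocyte-like and −0.49 in stellate- or fibroblast-like nuclei, each against 0.38 in T- or NK-like nuclei. For Tnfrsf1b it was −0.50 against 0.17 in macrophage-like nuclei. Sesn1 had 0.39 in hepatocyte-like, 0.11 in macrophage-like and 0.22 in T- or NK-like nuclei, each against −0.43 in B-like nuclei. Slc1a2 had −0.49 in hepatocyte-like and −0.54 in macrophage-like nuclei, each against 2.04 in B-like nuclei. Abcb4, Dmgdh, Pck1 and Slc1a2 are on hepatocyte lists, and hepatocyte RNA free in droplets of B-like nuclei was not tested.

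Among the other classes, Cotl1 had 0.96 in endothelial-like and 0.76 in stellate- or fibroblast-like nuclei, each against −0.18 in T- or NK-like nuclei. Ctsc had −0.39 in macrophage-like nuclei against 0.75 in endothelial-like and 0.87 in T- or NK-like nuclei. Gfod1 had 1.14 in stellate- or fibroblast-like and −0.28 in B-like nuclei, and Igfbp7 −1.10 in macrophage-like and 0.17 in stellate- or fibroblast-like nuclei. Tox had −0.72 in T- or NK-like nuclei against 0.19 in stellate- or fibroblast-like and 1.33 in B-like nuclei.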

How the results depend on the processing

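The alternative without the hepatocyte cluster of highest Gpc3 was chosen after seeing the data. With an arm of 1 library, the lone sample is assumed to vary like the other group. Of the values of main results under the alternatives, 151 stayed, 37 moved and 1 became a call. Among those of named genes, 2284 stayed and 149 became calls. Among those of lists, 365 stayed, 32 became calls, 38 lost a call and 8 turned. For genes and lists, stayed means that no call was gained, lost or turned, whatever the change in value. Brca1 in hepatocyte-like nuclei, at −1.04 to 0.57 with a library left out, counts as stayed. A share stayed if it moved by less than its SD. The causes were not tested, except where fewer libraries or genes entered by construction.

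For genes called, DESeq2 gave 23 in hepatocyte-like nuclei, 21 in all nuclei and 0 in each other class. Without the filter on low counts, edgeR called 2 in hepatocyte-like, 2 in all, 45 in endothelial-like, 69 in macrophage-like, 30 in stellate- or fibroblast-like, 18 in T- or NK-like and 32 in B-like nuclei; those in hepatocyte-like nuclei included Cacna1b, named after its values were seen. All deposited barcodes gave 3 in T- or NK-like and 1 in B-like nuclei. Leaving out each library gave 0 to 198 in hepatocyte-like, 0 to 182 in all, 0 to 587 in endothelial-like, 0 to 530 in macrophage-like, 0 to 406 in stellate- or fibroblast-like, 0 to 88 in T- or NK-like and 0 to 133 in B-like nuclei, each highest without the library labelled Brca1-KO replicate 1. The log2 fold change ranged from −1.04 to 0.57 for Brca1 and from −2.42 to −1.09 for Bhmt. The difference in the share of hepatocyte-like nuclei with a Bhmt UMI was −15.7 percentage points unthinned and −46.1 to −20.9 with a library left out.

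Lists called in hepatocyte-like nuclei numbered 0 with an estimated correlation, 0 with fry and 6 to 16 with a library left out. Those in other classes numbered 0, 0, 2 in thinned nuclei and 0 to 3 with a library left out. The direction turned for the carcinoma list in thinned nuclei (0.635) and for the Kupffer list with doublets kept (0.918) or all barcodes (0.971). It also turned for periportal genes without the library labelled Brca1-KO replicate 1 (adjusted p 0.0046 to 0.166 over the libraries left out), the urea cycle without replicate 2 (4.3e-11 to 0.878), acute phase without replicate 2 (0.030 to 0.309), ribosomal proteins without Brca1-WT replicate 2 (1.6e-13 to 0.765) and the T cell list without the library labelled Brca1-KO replicate 1 (0.252 to 0.840).

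Replicate numbers are shared between groups, but nothing pairs the samples: the deviations of same-numbered libraries had an r of −0.10 across genes, which are not independent replicates. With a replicate block, 0 genes were called in each class, 7 lists in hepatocyte-like nuclei and 4 in others, with log2 fold changes of −1.72 for Bhmt and −0.22 for Brca1. No cluster was named cholangiocyte-like, so no test was run there, and Leiden resolution 0.5 left the sum of all nuclei as it was. Counts limited which genes could be tested: 4199 passed the filter on low counts in B-like nuclei and 15089 in hepatocyte-like nuclei.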

Other observations

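All tests in this part were chosen only after the result was seen, and several other settings of the neighbour test and of the hepatocyte enrichment were tried before those given here.

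The hepatocyte-like nuclei of the library labelled Brca1-KO replicate 2 stood apart: 266 of 8675 genes were at least 2-fold from all 3 other libraries, against 59 and 12 in the Brca1-WT libraries and 49 in the library labelled Brca1-KO replicate 1. With each nucleus thinned to 1000 UMIs, 284 genes stood apart, against at most 83 in another library. Thinning evens out the counts per nucleus but leaves the expected proportions of its transcripts. It therefore does not decide whether depth of the nuclei is an explanation. Another time of feeding or of killing is a candidate explanation: 13 of 13 genes raised by fasting lay below the mean of the other 3 libraries, with a median log2 ratio of −1.17, while 2 and 2 did in the Brca1-WT libraries and 7 in the library labelled Brca1-KO replicate 1. Of 13 genes raised by feeding, 9 lay above and 4 below, with a median of 0.30 and Acacb at −1.71, which is a weaker and mixed result. Igfbp1 had 7.96 CPM against 77.6, 52.7 and 53.3 CPM, all 5 clock genes of the phase opposite to Dbp were below and all 6 in phase with it above; an effect of genotype in this library stays open as untested.

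Bhmt was lower in both libraries labelled Brca1-KO in hepatocyte-like nuclei and in each other class. A different mixture of hepatocyte clusters was argued against for the nuclei of shared clusters. Within 5 of 5 clusters shared by all libraries, both libraries labelled Brca1-KO lay below both Brca1-WT libraries. These clusters cover a small part of the library labelled Brca1-KO replicate 2, as 86.4% of its hepatocyte-like nuclei lay in clusters 4, 6 and 13. There the library labelled Brca1-KO replicate 1 had 3, 2 and 4 nuclei, too few for the same comparison. In the Gpc3-high cluster, Bhmt had 187 and 117 CPM in the Brca1-WT libraries. In the other classes free hepatocyte RNA in droplets is a candidate source: 100% of 20 hepatocyte-enriched genes with a fold of 2 or more kept their sign in endothelial-like nuclei, and the trend over 640 hepatocyte-enriched genes of any fold gave −1.01 for Bhmt, where −0.93 was seen. Genotype, and a further difference between the mice, stay open for hepatocyte-like nuclei.

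The genes of lowest p in the labelled split held many neighbouring pairs. Variants linked to Brca1 or to the strain background could bring neighbouring genes together: the 100 genes of lowest p held 33 neighbouring pairs, against a mean of 13 in 1000 permutations (p = 0.001, the smallest they can give). The other 2 splits held 26 and 20 pairs, so the excess is not particular to the labels, and the explanation stays open.

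No test bore on whether the library labelled Brca1-KO replicate 1 carries the right genotype label. Its Brca1 level, 18.5 CPM, went against the label, while its Bhmt level, 717 CPM against 1877 and 1190 CPM in the Brca1-WT libraries, went with it. Across 15089 genes in hepatocyte-like nuclei, which are not independent replicates, the correlation of its log CPM was 0.989 with Brca1-WT replicate 2, 0.981 with Brca1-WT replicate 1 and 0.972 with the library labelled Brca1-KO replicate 2, where that between the Brca1-WT libraries was 0.983. The labelled split gave 495 genes with an unadjusted edgeR p below 0.05 and 13 with a gap of at least 2-fold. Parting this library with Brca1-WT replicate 2 gave 1167 and 42. With Brca1-WT replicate 1, the counts were 505 and 20. Gaps of at least 4-fold numbered 3, 0 and 2 in the same order. These counts do not decide the label.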
